A study of Mus musculus with 5 samples.

How the data were processed

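The series measured total RNA of regulatory T (Treg) cells, the CD4 T cells that carry the transcription factor Foxp3 and restrain immune responses. The cells were sorted as CD4+YFP+ from C57BL/6 mice in which Foxp3-driven Cre marks Treg cells with a yellow fluorescent protein. There were 5 libraries in 4 groups. The groups, taken from the labels, were wild type (WT) at 21 days (1 library), WT at 6 weeks (1 library), a Treg deletion of Malt1 at 21 days (KO, 1 library), and mice at 6 weeks with 1 floxed Malt1 allele and 1 allele with the C472A substitution, which the labels describe as loss of protease activity (KI, 2 libraries). Malt1 encodes a paracaspase that signals to NF-kB as part of a complex named CBM. The labels do not say that libraries came from separate animals, so p-values of single genes measure the spread between these samples, which may be technical.

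Reads were processed by the authors with CASAVA, HISAT2 2.1.0 and Cufflinks 2.2.1 on mouse build GRCm38, per the submitters' processing notes, which give no order or settings. The deposited values are gene-level FPKM (fragments per kilobase of transcript, normalized to the mapped fragments) with a lower and an upper bound and a status for each gene, per the file headers. Each file holds 38130 entries for 38109 gene IDs, and 39 entries share an ID. Status differed from OK in 2 libraries, for Nlrc5 in KI replicate 1 and Arhgef6 in KI replicate 2. Symbols are those of the files, and 7936 of the 36282 entries with an ID in GENCODE M21 carry another symbol there. That release was used for gene types and for matching 10 of 529 list members by their current symbol. The list members Cox4i1, Mvd and Rpl13 were not analysed here. Starts in the files are counted from 0, since 27652 of 36282 entries match the GENCODE start after adding 1, and coordinates here are counted from 1. The annotation release, strand setting and read type are not given in the sources used here. Without strand, reads of overlapping or antisense genes cannot be separated, and members of multigene families can share reads.

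FPKM hold no counts, so depth was estimated from the bounds, which lie 2 standard errors from each value. The estimated depth was 30.9 M fragments (M for mega) in WT at 21 days, 7.26 M in WT at 6 weeks, 8.28 M in KO, and 27.2 and 26.4 M in KI replicates 1 and 2. These are approximate, with quartiles over genes of 5.999 to 8.011 M in WT at 6 weeks and 25.2 to 34.4 M in WT at 21 days. The length that Cufflinks subtracts from a transcript, estimated in the same way, was 223, 156, 154, 228 and 231 nt in the same order. It raises FPKM of transcripts near the fragment length by different amounts in the libraries, so values of short RNAs such as U2, U1 or mt-Tp are uncertain. The bounds cover counting and assignment error within a library only.

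FPKM were divided by a median-of-ratios factor per library, from 9874 genes at FPKM of 1 or more in all 5 libraries (0.876, 1.15, 1.15, 0.868 and 1.01 in the order above), and are called scaled FPKM. Differences are on the scale log2(scaled FPKM + 1), which understates changes of low genes. The 11296 genes with a mean scaled FPKM of at least 1 over the 5 libraries were tested, of which 9872 are protein coding. KI was compared with WT at 6 weeks by limma 3.58.1 (R 4.3.3) with trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. That fit has 1 residual degree of freedom, from the KI pair, and assumes that the lone WT library varies as the KI libraries do. A count by size was made beside it, of genes past 2-fold in both KI libraries in the same direction. KO against WT at 21 days and WT at 6 weeks against WT at 21 days have 1 library per group, so they have no replicate check and were counted by size. For KO a limma fit of the 4 group means was made beside it, in which the spread comes from the KI pair alone.

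The limma step was tested on simulated data with 200 changed genes, 50 each at 2-, 4-, 8- and 16-fold. Over 11296 genes it called 0% of the changed genes at any size and 0 genes in all, so it had no power there for changes of those sizes. Over the 9870 protein-coding genes with status OK it recovered 2% of 2-fold, 84% of 4-fold, 92% of 8-fold and 100% of 16-fold changes. In that run 17 of 156 calls were of unchanged genes, above the nominal 5%, and the tolerance set for this check was widened after that share was seen. With no gene changed it made 0 calls.

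There were 34 gene lists, fixed by hand, for signalling through Malt1, Treg and T helper states, stress, interferon, metabolism, cell division, sex and other cell types, and 32 had at least 3 tested genes. In KI they were tested with camera (limma) at a preset correlation of 0.01, and again with an estimated correlation and with fry. At the preset correlation camera compares the genes of a list with the other genes, so its p-values do not measure the spread between samples. With an estimated correlation camera relies on the 1 residual degree of freedom of the fit against either WT library. It could then hardly call any list, so a lack of calls there decides nothing. In KO, in KI beside camera and between the WT ages, the median of each list was placed among 10000 random lists. These had the same size and were matched on mean expression, as a description of these libraries. The genes named are the 10 higher and the 10 lower with the largest difference for KI and for KO and 5 of each for the WT ages, in KI with both libraries past 2-fold and calls at the threshold first, then genes from a fixed set of 23, some of which are not given in the text, and the largest 2 to 4 members of each list described. The rule leaves out genes with no symbol, symbols of Gm and digits, ending in Rik or starting with Mir, Snor or n-R, histones, pseudogenes of ribosomal proteins, receptor and antibody segments, the mitochondrial genome, entries with a status other than OK, and genes whose higher group level was under 5 scaled FPKM. It reads symbols, so genes under clone names, such as AL929268.1 and RP24-281K23.1, stay in whatever their type. Lists, tests, the naming rule and most alternatives were fixed before the data were examined.

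Alternatives were FPKM as deposited, scaling to TPM, quantile normalization, pseudocounts of 0.1 and 5, other filters, thresholds and folds, other limma settings, and leaving out each KI library. Chosen after seeing the data were the restriction to protein-coding genes, the naming rule applied to these, a comparison with the WT library of the same library set, and counts against both WT libraries. A library set here means the libraries that group by depth and correlation, WT at 21 days with both KI libraries, and WT at 6 weeks with KO. Groups stayed as labelled throughout. Figures were drawn with matplotlib 3.10.9, and other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.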

Results

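Gene expression was measured by RNA sequencing in sorted CD4+YFP+ Treg cells of 5 libraries, WT at 21 days, WT at 6 weeks, KO at 21 days and 2 KI libraries at 6 weeks. The design asks how Treg cells differ from WT when Malt1 is deleted and when, per the labels, its protease activity is inhibited. KI carries 1 floxed and 1 C472A allele, so protease activity need not be its only difference from WT. Estimated depth ranged from 7.26 M fragments in WT at 6 weeks to 30.9 M in WT at 21 days. WT at each age and KO had 1 library each, so differences for KO and between the WT ages have no replicate check.

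Malt1 (ENSMUSG00000032688, chromosome 18, 65430963 to 65478823, GRCm38) was higher in both KI libraries than in either WT library, and in KO it lay between the WT libraries. Its scaled FPKM was 27.0 in WT at 21 days, with bounds of 26.1 and 27.8, and 15.2 in WT at 6 weeks, with bounds of 14.1 and 16.4. The KO library had 17.6, with bounds of 16.4 and 18.8, and the KI libraries had 55.9 and 37.8, or 46.9 ± 12.8 (SD, n = 2). KI lay 1.53 above WT at 6 weeks on the log2 scale (SE 0.335), which missed the threshold in limma (adjusted p = 0.426). KO lay at -0.59 against WT at 21 days and at 0.20 against WT at 6 weeks, so the level of this gene does not separate the library labelled KO from WT. A deletion of some exons need not lower a value summed over the gene, and the files give no exon values.

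The libraries fell into sets that crossed age and genotype. WT at 21 days was closest to the KI libraries at 6 weeks, with a Pearson r across 11296 genes of 0.951 and 0.943. WT at 6 weeks was closest to the library labelled KO at 21 days, with r = 0.939. The r between the WT libraries was 0.910, that between the KI libraries 0.930, and WT at 6 weeks had r = 0.887 and 0.901 with KI of its own age. The first principal component, with 50.6% of the variance over protein-coding genes, separated WT at 21 days and both KI libraries from WT at 6 weeks and KO. Depth split in the same way, 26.4 to 30.9 M fragments against 7.26 to 8.28 M. Each age-matched comparison therefore runs across the sets, and the difference from the WT library of the same set, which has the other age, is given beside it.

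**Figure D1:**
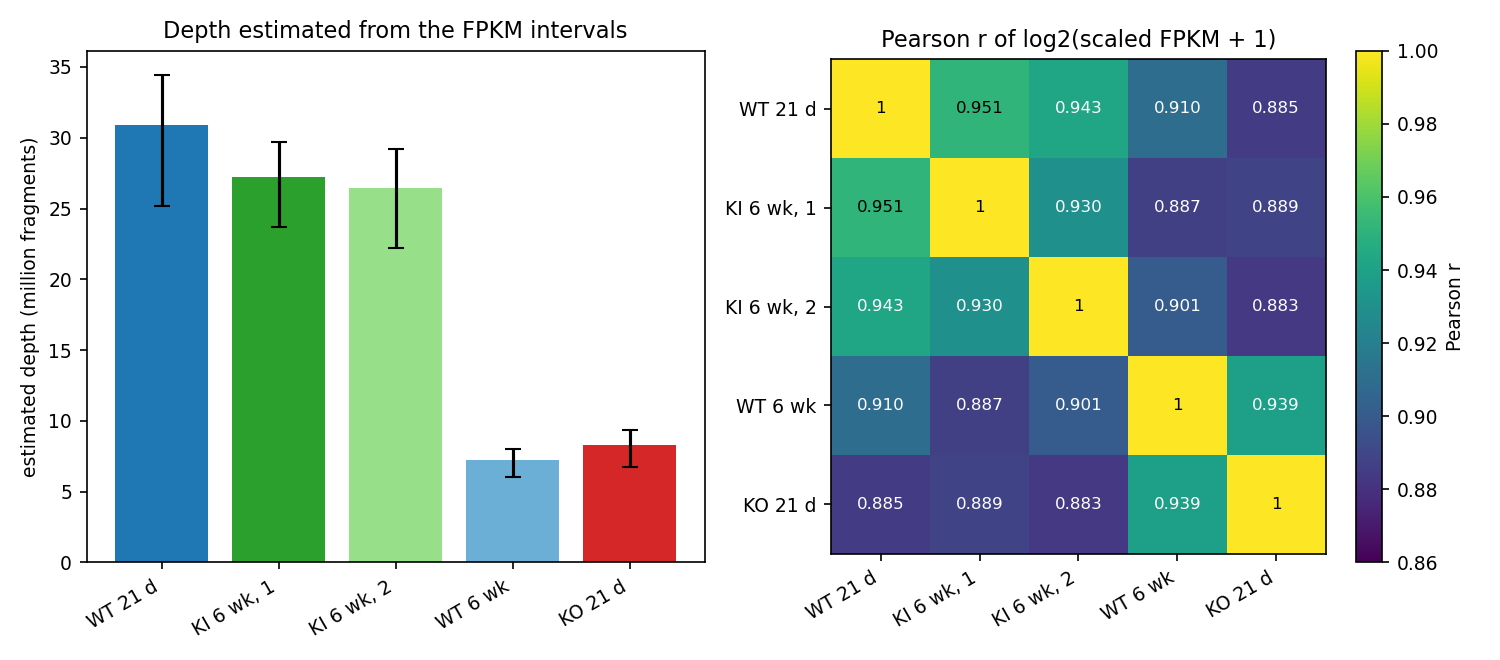
Left, estimated depth of each library in M fragments as bars, with quartiles over genes as error bars. Right, Pearson r of log2(scaled FPKM + 1) across 11296 genes for each pair of libraries, where WT at 6 weeks and KO have r = 0.939 and the WT libraries 0.910.

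In KI at 6 weeks, the lists of Treg identity genes lay above WT of the same age and those of the type I interferon response and of B cells below it. These calls, made by camera at a preset correlation, were lost with an estimated one. That second run rests on 1 residual degree of freedom and could hardly call any list, so the loss decides nothing. Cdk6, a cell cycle kinase, rose to 25.6 and 24.1 scaled FPKM from 3.52 in WT, and Hipk2, a kinase that acts on p53, rose to 28.2 and 32.7 from 4.63. Siglech, a receptor of plasmacytoid dendritic cells, had 16.8 in WT at 6 weeks and 0 and 0.149 in KI, but only 0.294 in WT at 21 days and 1.24 in KO. Spib, a transcription factor of B cells and plasmacytoid dendritic cells, had 7.498 in WT at 6 weeks and 0.127 and 0.116 in KI. It had 0.862 in WT at 21 days and 0.898 in KO, so both genes were high in WT at 6 weeks alone. Klrg1, a receptor of short-lived effector lymphocytes and terminal effector Treg cells, had 37.3 in WT at 6 weeks, 21.3 in WT at 21 days and 0.699 and 7.16 in KI.

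Over all 11296 genes limma called 1 gene at the threshold, the mitochondrial tRNA gene mt-Tp (adjusted p = 0.0432), at 7832 scaled FPKM in WT at 6 weeks and listed at 0 in both KI libraries. At an unadjusted p under 0.05 it had 1211 genes, 650 higher and 561 lower. Over protein-coding genes, a restriction chosen after the data were seen, limma called 15 genes, 5 higher and 10 lower, with 1193 at an unadjusted p under 0.05. The 5 higher were mt-Atp8, Lsm5, Cdk6 (log2 difference 2.52, SE 0.310, adjusted p = 0.0348), Hipk2 (2.48, SE 0.306, adjusted p = 0.0348) and Ece1, the endothelin converting enzyme (2.56, SE 0.337, adjusted p = 0.0440). The 10 lower were Siglech (-4.05, SE 0.381, adjusted p = 0.0254), Ctse, Ly6d, D13ERTD608E, Pld4, Gm11273, PPP4R2, Rnase6, Gm10197 and Spib (-2.92, SE 0.378, adjusted p = 0.0423). Against WT at 21 days, the WT library of the same set, limma called 0 genes over all genes and 0 over protein-coding genes, with 240 and 202 at an unadjusted p under 0.05. There Cdk6 and Hipk2 lay at 1.55 and 1.31, and Ece1 and Siglech at -0.03 and -0.27. Mt-Atp8 followed the library sets, with 1272 and 1114 scaled FPKM in KI and 1179 in WT at 21 days. It had 56.8 in WT at 6 weeks and 35.7 in KO.

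By size alone, 656 genes were past 2-fold in both KI libraries against WT at 6 weeks, 340 higher and 316 lower, and 14 genes were past 2-fold in opposite directions in the KI pair. With FPKM as deposited the split was 217 higher and 539 lower, with a median over all genes of -0.26. The count was 134 against WT of the same set, 45 higher and 89 lower, and 71 against both WT libraries, 32 higher and 39 lower. For comparison, 744 genes were past 2-fold between the KI libraries. Splits of the same 4 libraries that mix the genotypes gave 109 genes (WT at 21 days and KI replicate 1 against WT at 6 weeks and KI replicate 2) and 34 genes (the KI libraries exchanged), beside the 71 of the genotype split. Of the 20 genes that the naming rule took, 12 are not protein coding, among them U2, U1, U4, 7SK and Metazoa_SRP, which are short RNAs listed at or near 0 in WT at 6 weeks or in KI. U2 (ENSMUSG00000065251) had 724 and 522 in KI, 441 in WT at 21 days and was listed at 0 in WT at 6 weeks and KO. The protein-coding genes it took were Lsm5, Areg, Bhlhe40 and Ece1 on the higher side and Tyrobp, Siglech, Ly6d and H2-Aa on the lower. Areg, an EGF receptor ligand linked to tissue repair by Treg cells, had 40.4 and 9.04 in KI, 1.37 in WT at 6 weeks and 14.2 in WT at 21 days. Tyrobp, an adaptor of myeloid and NK cell receptors, had 4.39 and 0.116 in KI, 50.1 in WT at 6 weeks and 1.24 in WT at 21 days. Of the 20, 12 had the same direction against WT of the same set and 0 were past 2-fold there. The rule applied to protein-coding genes added Cdk6, Hipk2, Pydc4, Neb, Fam160a1, Plagl1, D13ERTD608E, Pld4, H2-Ab1, Klrg1, PPP4R2 and Rnase6, and 5 of its 20 genes were past 2-fold in the same direction against WT of the same set.

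Over protein-coding genes, 47 were past 2-fold against both WT libraries, and the mixed splits gave 57 and 18. Among the 47, named after their values were seen, was Il1r2, a decoy receptor for interleukin 1, on the higher side. Il1r2 had 50.5 and 45.1 in KI against 11.4 and 13.6 in WT at 6 weeks and 21 days. On the lower side were Ccr9, a gut homing receptor, Cd86, a ligand of CD28 and CTLA-4, Cxcr6, Ccr6, Tox2 and Dtx1. Cd86 had 2.67 and 2.46 in KI against 9.63 and 11.1 in WT, and Dtx1 had 20.6 and 22.6 against 65.7 and 51.0.

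Of the 32 gene lists tested in KI against WT at 6 weeks, camera at the preset correlation called 11, 4 up and 7 down, and 0 were called with an estimated correlation, where the lowest adjusted p = 0.758, or by fry. Placed among random lists, 20 of 32 medians in KI lay outside the central 95%, and 18 did between the WT libraries, which share a genotype. Treg identity had 13 of 15 genes higher with a median of 0.85 (adjusted p = 9.6e-05, 0.758 with an estimated correlation). Its members included Lrrc32, which presents latent TGF-beta, at 1.78, Itgae at 1.52, Ikzf2 at 1.13 and Ctla4 at 1.10. Against WT at 21 days, where 13 of 15 genes were higher in KI, Ikzf2 lay at 0.24 and Ctla4 at -0.31. Foxp3 had 70.1 and 73.6 in KI, 39.5 in WT at 6 weeks and 70.7 in WT at 21 days. The interferon-gamma response had 12 of 18 genes higher (median 0.49, adjusted p = 0.0491, 0.758 with an estimated correlation), with Cxcl10 at 1.98, Cd274 at 1.59 and Iigp1 at 1.37. NF-kB target genes had 23 of 30 genes higher (median 0.34, adjusted p = 0.0491, 0.772 with an estimated correlation, and 0.0522 with FPKM as deposited), with Rel at 1.61, Bcl2a1a at -1.53 and Tnfaip3 at 1.02, which was 1.98 and 0.06 in the KI replicates. The type I interferon response had 19 of 20 genes lower (median -1.09, adjusted p = 4.6e-06, 0.758 with an estimated correlation), with Ifit3 at -1.71 and Bst2 at -1.54. Oxidative phosphorylation had 25 of 27 genes lower (median -0.37, adjusted p = 9.6e-05, 0.758 with an estimated correlation), and cytoplasmic ribosomal proteins 33 of 36 (median -0.31, adjusted p = 0.0497, 0.820 with an estimated correlation). The 13 mitochondrially encoded genes were all higher in the KI mean (median 0.69, adjusted p = 0.00578, 0.772 with an estimated correlation), led by mt-Atp8 at 4.37. The medians in KI replicates 1 and 2 were 0.77 and 0.73 for Treg identity, 0.41 and 0.42 for the interferon-gamma response, 0.68 and 0.16 for NF-kB target genes, and -1.25 and -0.69 for the type I interferon response. They were -0.46 and -0.29 for oxidative phosphorylation, -0.11 and -0.47 for cytoplasmic ribosomal proteins, and 1.13 and 0.25 for mitochondrially encoded genes, of which 11 of 13 were higher in replicate 2. Leaving out 1 KI library thus moves several of these medians by more than 1.5 times. The estimated correlation of Treg identity was -0.029, below the preset 0.01. The loss of its call thus came from the 1 residual degree of freedom, not from a larger estimated correlation. That estimate itself rests on 1 residual degree of freedom, so it cannot show whether the genes move together. With both WT libraries as control the estimate was 0.173. Mt-Atp8, which led the mitochondrially encoded list, was as high in WT at 21 days (1179 scaled FPKM) as in KI (1272 and 1114).

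Lists of other cell types were also lower in KI than in WT at 6 weeks. All 5 tested B cell genes were lower (median -1.89, adjusted p = 3.0e-05, 0.758 with an estimated correlation), with Cd79b, part of the B cell receptor, at -2.06. All 10 myeloid genes (median -1.93, adjusted p = 9.6e-05), 3 NK cell genes (median -1.58, adjusted p = 0.00671) and 4 erythroid and platelet genes (median -1.97, adjusted p = 0.0147) were lower, each with an adjusted p = 0.758 with an estimated correlation. In KI replicates 1 and 2 the medians were -1.58 and -2.08 for B cell, -1.32 and -2.61 for myeloid, -1.52 and -1.63 for NK cell, and -1.36 and -2.91 for erythroid and platelet genes. These genes were mostly highest in WT at 6 weeks among all 5 libraries, 9 of 10 in the myeloid list, 4 of 4 in the erythroid list, 4 of 5 in the B cell list and 14 of 20 in the type I interferon list, but only 1 of 3 in the NK cell list. Adjusted over the list alone, limma called 12 genes in 6 lists, 5 in the B cell list, 3 in NK cell, 2 in cytotoxic granule and 1 each in erythroid and platelet, mitochondrially encoded and plasma cell, with Gzma counted in both NK cell and cytotoxic granule. Over all genes it called 0 of them, and all 12 had an unadjusted p under 0.05.

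Against WT of the same set, camera called 12 lists in KI, 3 up and 9 down, and 0 with an estimated correlation, where the lowest adjusted p = 0.938. Of these, 5 were called in the same direction against both controls, Treg identity and the interferon-gamma response up, and the type I interferon response, B cell and cytoplasmic ribosomal proteins down. Their medians against WT of the same set were 0.24, 0.36, -0.45, -1.15 and -0.32. The mitochondrially encoded list was called down there (median -0.79, adjusted p = 3.6e-04), the opposite direction. The medians of the myeloid, NK cell and erythroid and platelet lists turned to 0.32, 0.05 and 0.18 there, and these lists were not called (adjusted p = 0.513, 0.776 and 0.801). NF-kB target genes, at 0.02, and oxidative phosphorylation, at -0.06, were not called either (adjusted p = 0.801 and 0.241). Proliferation was called up (median 0.80, adjusted p = 3.6e-07), and against WT at 6 weeks its median was -0.06 in KI replicate 1 and 1.09 in replicate 2. Heat shock and dissociation (-0.66), immediate early TCR response (-0.65), Tfh (-0.89), Th17 (-0.81) and chemokine and homing receptors (-0.24) were called down.

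The remaining lists were not called against WT at 6 weeks. CBM complex and MALT1 substrates had a median of 0.53 (adjusted p = 0.0654), with Malt1 at 1.53, Rc3h1 at 1.15 and Card9 at -1.13. Regnase-1 and Roquin target transcripts, RNAs whose decay MALT1 protease opposes, had 0.63 (adjusted p = 0.112), with Rel at 1.61 and Irf4 at 1.55. Effector Treg had 0.46 (0.0624), Th2 0.63 (0.0654), proliferation 0.47 (0.0654), sex of the animal 0.48 (0.112), coinhibitory receptors 0.47 (0.624), glycolysis 0.21 (0.279) and apoptosis regulators 0.13 (0.422), as median and adjusted p. Lower medians were those of pan T cell at -0.50 (0.0622), Tfh -0.70 (0.116), heat shock and dissociation -0.43 (0.0654), cytotoxic granule -0.49 (0.116), plasma cell -0.43 (0.611), resting T cell -0.33 (0.261), cholesterol synthesis -0.29 (0.140), unfolded protein response -0.28 (0.261) and Th17 -0.18 (0.691). For Th1 (0.13, 0.990), chemokine and homing receptors (0.13, 0.774) and immediate early TCR response (-0.19, 0.961), median, mean and test differed in sign. The CD8 T cell and thymocyte list (median -0.81) and the stromal and epithelial list (median -0.03) had 2 tested genes each and no test. Against WT of the same set several of these medians changed sign, those of Regnase-1 and Roquin target transcripts to -0.17 (with Rel at -0.83 and Irf4 at 0.69), effector Treg to -0.05, coinhibitory receptors to -0.14, cytotoxic granule to 0.08, plasma cell to 0.18 and stromal and epithelial to 0.28. CBM complex and MALT1 substrates had 0.10 there, Th2 0.16, sex of the animal 0.16, glycolysis 0.17, apoptosis regulators 0.05 and Th1 0.05. Pan T cell had -0.24, resting T cell -0.25, cholesterol synthesis -0.05, unfolded protein response -0.13, and CD8 T cell and thymocyte -0.43.

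**Figure D2:**
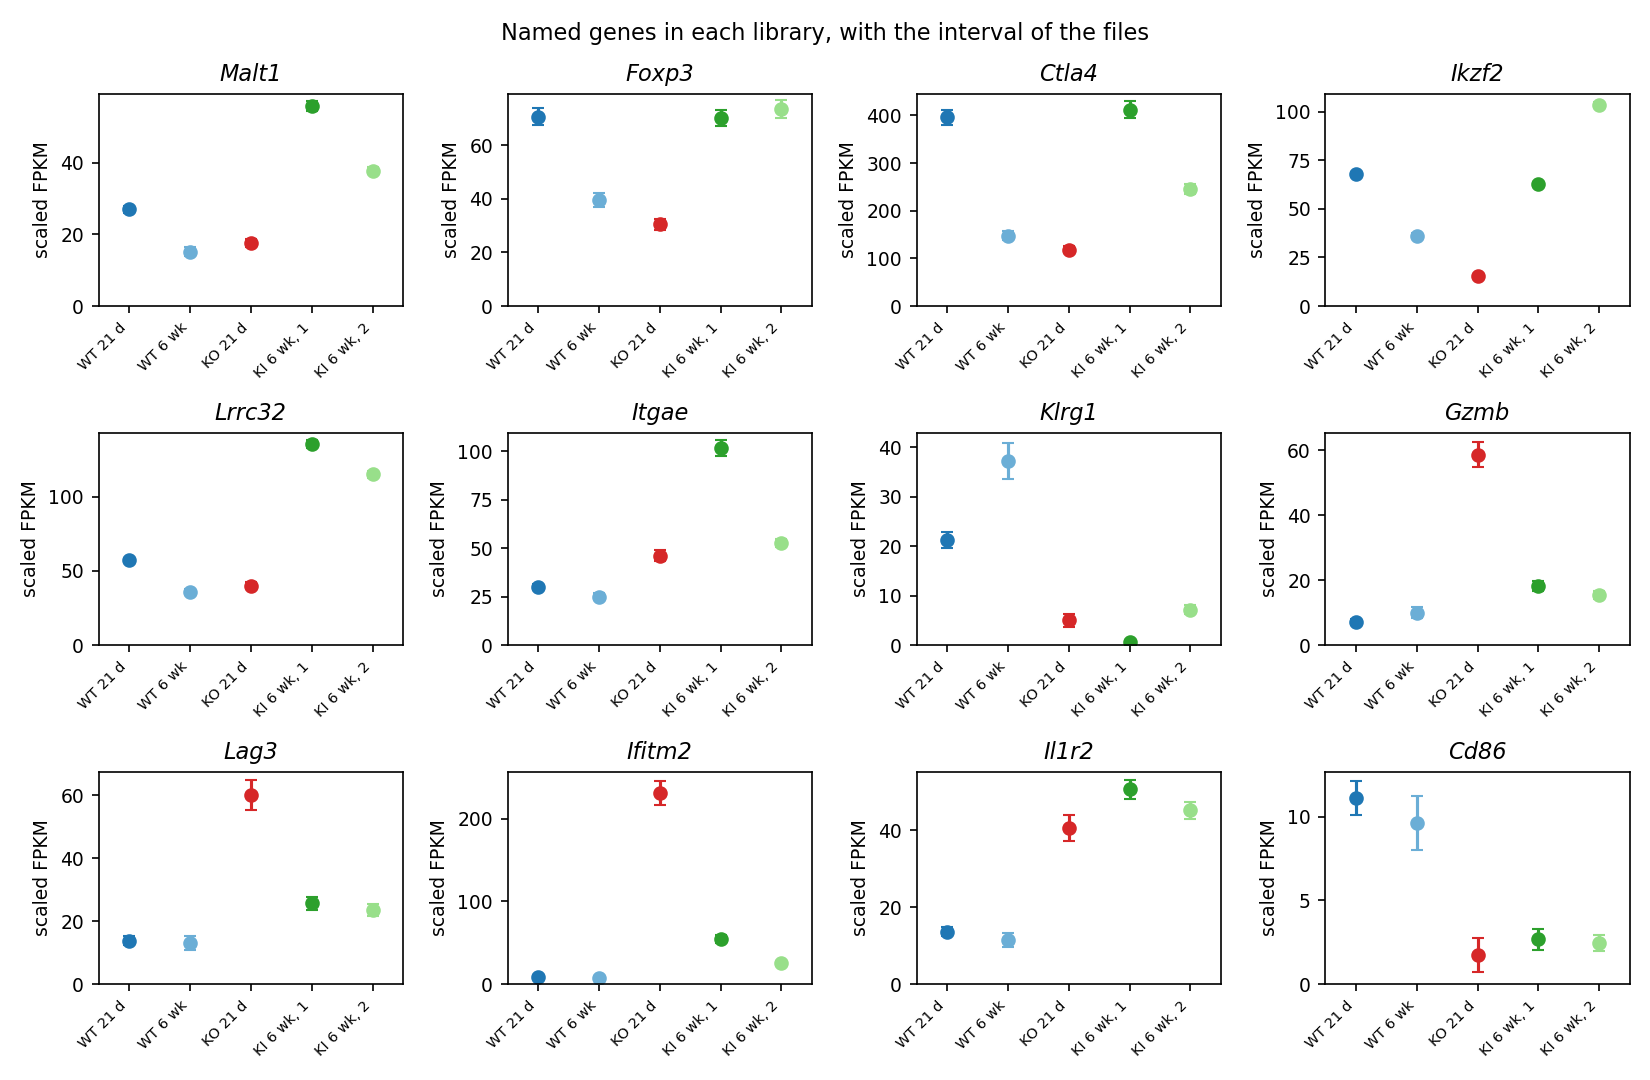
Scaled FPKM of 12 genes in each of the 5 libraries as points, with the bounds of the files as error bars, on linear axes from 0. Il1r2 lies at 40.5 to 50.5 in the KO and KI libraries and at 11.4 and 13.6 in WT, while Foxp3 and Ctla4 are higher in WT at 21 days and KI than in WT at 6 weeks and KO.

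In the library labelled KO, the lists of cytotoxic granule and proliferation genes had higher medians than in either WT library, as had the NK cell list, which shares Gzma, and Ifitm2, Lgals3 and Gzmb were among the genes higher than in both. Ifitm2, which restricts virus entry, had 230 scaled FPKM against 8.69 in WT at 21 days and 7.52 in WT at 6 weeks. Lgals3, a galectin, had 81.9 against 3.44 and 11.4, and Gzmb, the granzyme B gene, had 58.7 against 7.13 and 9.93. Il4, a T helper 2 cytokine, had 14.5 against 0.675 and 0.712. Foxp3 had 30.5 in KO, 70.7 in WT at 21 days and 39.5 in WT at 6 weeks, and Ikzf2, the Treg transcription factor Helios, had 15.4, 68.0 and 36.3.

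Against WT at 21 days, 1613 genes were past 2-fold, 693 higher and 920 lower. With FPKM as deposited the split was 1509 higher and 493 lower, with a median over all genes of 0.35. The count was 632 against WT at 6 weeks, the WT library of the same set, 373 higher and 259 lower, and 351 against both WT libraries, 245 higher and 106 lower. The naming rule took Trnp1, Ifitm1, Ifitm2, Ifitm3, Lgals3 and the short RNAs snoU13, SCARNA21, U6 and 2 Metazoa_SRP genes as higher. Trnp1 had 36.3 in KO and was listed at 0 in both WT libraries. On the lower side it took 10 genes that are not protein coding, U2, U1, U4, U4atac, Vault, SCARNA14, SCARNA15 and RP24-281K23.1, all listed at 0 in KO and in WT at 6 weeks. Applied to protein-coding genes, it added Ctse, Lgals7, Slpi, PPP4R2 and Ccl1 as higher, and took as lower Nr4a3 (-3.46), Nr4a2 (-3.15), Dusp4 (-3.36), Rel (-3.07), Pydc4, Plagl1, Zbtb10, Trp53inp2, Tgif1 and Itga4 (-2.62). Nr4a3 and Nr4a2, nuclear receptors induced by T cell receptor signals, lay at -0.81 and 0.20 against WT of the same set, Rel, an NF-kB subunit, at -0.64 and Itga4, an integrin chain, at -1.32. Of the 20 genes that the rule took over all genes, 9 had the same direction against WT of the same set and 8 were past 2-fold. Of the 20 protein-coding genes, 19 had the same direction against WT of the same set and 9 were past 2-fold. A limma fit of KO against both WT libraries as replicates regardless of age called 8 genes, all higher, over all genes and 5 over protein-coding genes, Ifitm2 (4.67, adjusted p = 0.0275), Lgals7, Il4 (3.20, adjusted p = 0.0490), Ccl1 and Gm20418, with 539 and 557 at an unadjusted p under 0.05. As KO has 1 library, the spread in that fit comes only from the KI pair and the WT pair, and the WT libraries lie in different library sets. In a fit of 4 group means limma called 0 genes for KO against WT at 21 days, with 1171 at an unadjusted p under 0.05, and its spread comes from the KI pair alone.

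Of 32 lists, 19 had a median in KO outside the central 95% of random lists against WT at 21 days, 8 high and 11 low, and 10 were outside in the same direction against both WT libraries. Between the WT libraries, which share a genotype, 18 of 32 were outside, so the count for KO is close to that without a difference in genotype. Proliferation had 31 of 32 genes higher (median 0.86, percentile 100, and 0.52, percentile 100, against WT of the same set), with Cdk1 at 2.06 and Cdc20 at 1.70. Also high against both were Th1 (0.70, and 0.52 against the same set, with Nkg7 at 1.87 and Tbx21 at 1.12), the interferon-gamma response (0.58 and 0.38, with Iigp1 at 1.68), cytotoxic granule (1.01 and 0.55, with Gzmb at 2.88 and Gzma at 2.64) and plasma cell (0.69 and 0.66). Low against both were Th17 (-1.59 and -0.99, with Rora at -2.39 and Ccr6 at -1.81), B cell (-0.78 and -1.14), resting T cell (-0.45 and -0.35), the type I interferon response (-0.30 and -0.93, with Oas1a at -1.44) and sex of the animal (-0.85 and -0.53). CBM complex and MALT1 substrates had -0.54 (percentile 0.370) against WT at 21 days and -0.05 (percentile 35.7) against the same set, immediate early TCR response -0.69 and -0.17, and mitochondrially encoded genes -1.65 and -0.10. Regnase-1 and Roquin target transcripts had -0.41 (percentile 1.87) and -0.16 (percentile 6.03), NF-kB target genes -0.16 (percentile 8.76) and 0.07 (percentile 92.8), and Treg identity -0.24 (percentile 5.80) and 0.05 (percentile 74.8). NK cell had 1.23 (3 of 3 genes higher, percentile 98.1) and 0.52 (percentile 89.4), oxidative phosphorylation 0.46 and 0.11 and heat shock and dissociation -0.52 and -0.14. Effector Treg and myeloid cell turned from -0.27 to 0.47 and from 0.61 to -1.69. Coinhibitory receptors had 0.16 (percentile 74.6) against WT at 21 days and 0.49 (percentile 100) against the same set, with 7 genes higher and 4 lower in each. Of its members, Lag3 and Havcr2 lay at 2.04 and 2.01 against WT at 21 days and at 2.12 and 1.73 against the same set. Ctla4 lay at -1.73 and -0.32.

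**Figure D3:**
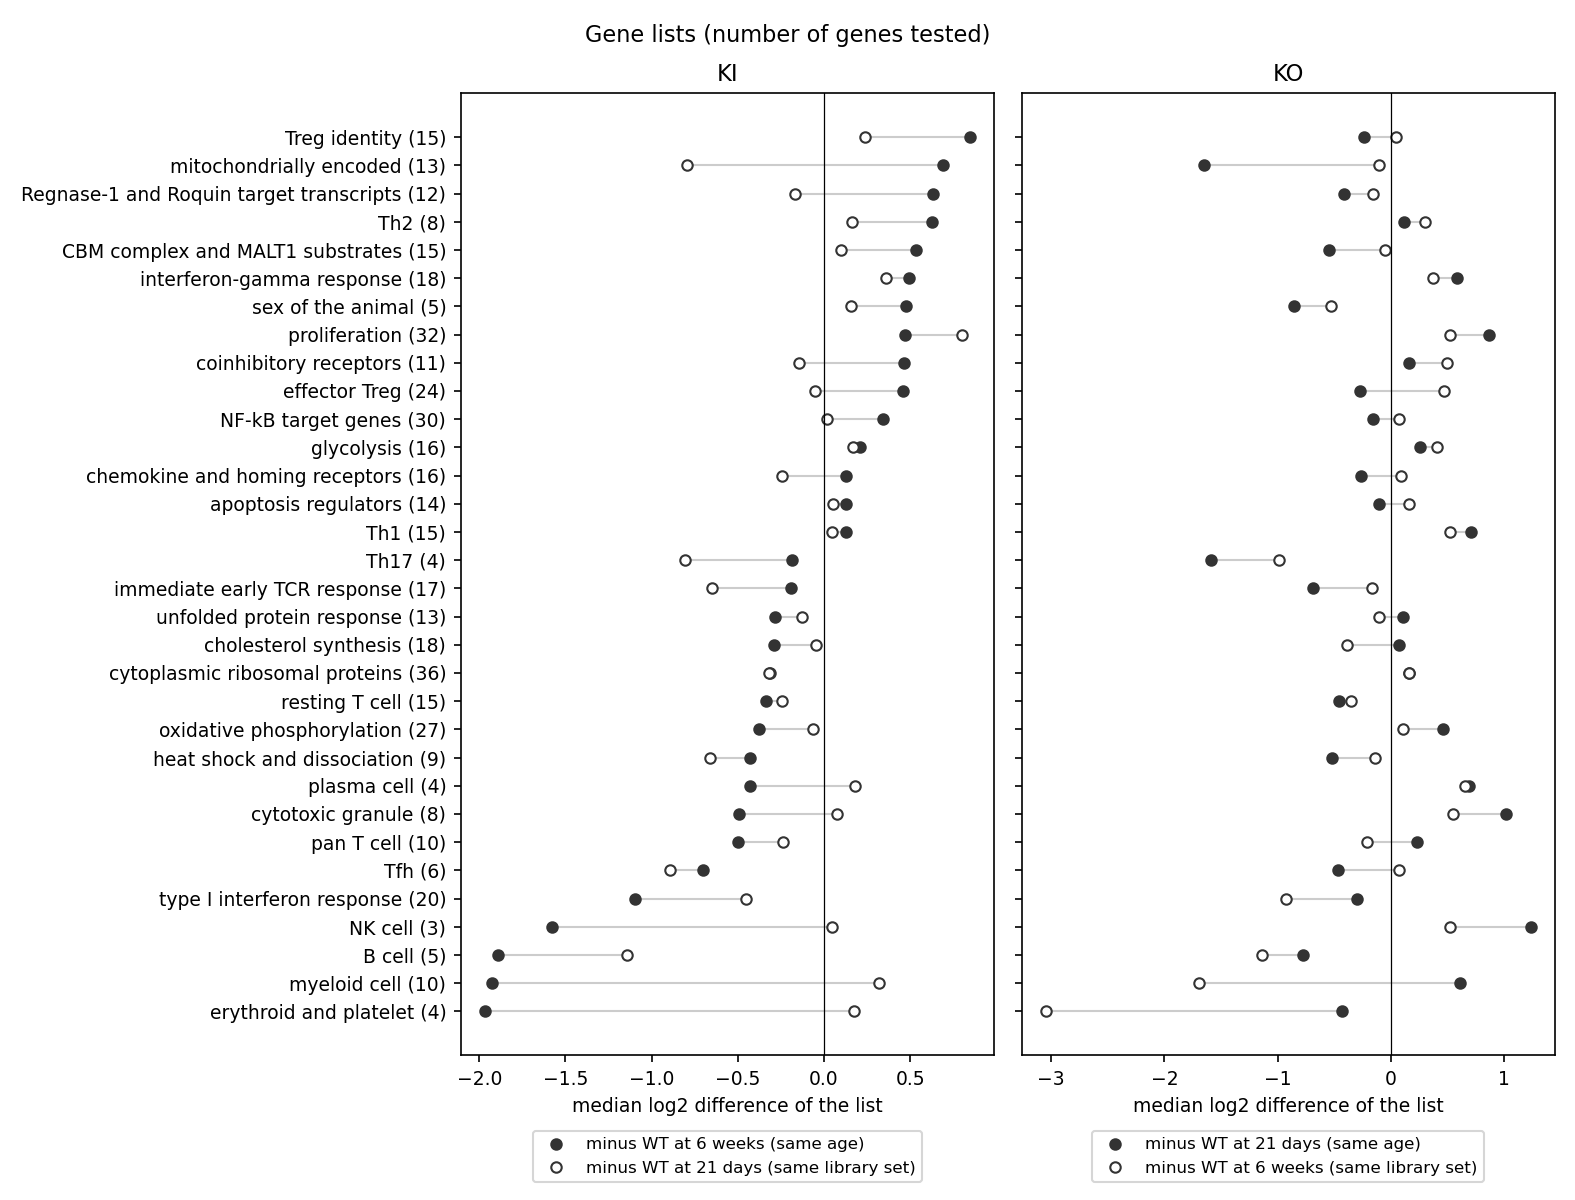
Median log2 difference of each of 32 gene lists, left for KI and right for KO, against WT of the same age (filled) and against WT of the same library set (open), with the number of genes tested in parentheses. The myeloid list lies at -1.93 and 0.32 in KI and at 0.61 and -1.69 in KO.

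Between the WT libraries, the lists of myeloid and of erythroid and platelet genes were higher at 6 weeks and that of mitochondrially encoded genes was lower. Tyrobp had 50.1 at 6 weeks and 1.24 at 21 days, Siglech 16.8 and 0.294, and Pld4 14.1 and 0.392. Nr4a2 had 2.89 and 38.8, and Maff, a small Maf transcription factor, 3.56 and 29.5. By size 967 genes were past 2-fold, 382 higher and 585 lower at 6 weeks, and with FPKM as deposited 988 higher and 340 lower. Over protein-coding genes the count was 525. The naming rule took only genes that are not protein coding, Metazoa_SRP, U4, U1 and AL929268.1 as higher and Scarna17, U2, RP24-281K23.1, U4atac and SCARNA15 as lower. Among protein-coding genes it took Tyrobp, Siglech, D13ERTD608E, Pld4 and PPP4R2 as higher and Lsm5, Nr4a2, Pydc4, Bhlhe40 and Maff as lower. The list medians were 2.12 for myeloid cell, 2.35 for erythroid and platelet, 0.56 for the type I interferon response and -1.49 for mitochondrially encoded genes. The immediate early TCR response had -0.23, with 7 genes higher and 10 lower, inside the central 95% of random lists.

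The differences of KO and KI were set side by side to see whether both genotypes differ from WT alike. Against WT of the same age they ran in opposite directions, and against WT of the same set they ran in the same direction. The correlation across genes, which are not independent replicates, was -0.445 (Pearson) and -0.456 (Spearman) against WT of the same age, and 0.190 and 0.294 against WT of the same set. With KI replicate 1 or 2 alone, the Pearson r against WT of the same set was 0.251 or 0.068. Over protein-coding genes the Pearson r was -0.396 and 0.406, and the second was 0.387 or 0.271 with KI replicate 1 or 2 alone. The pairs of differences share no WT library. The sets were read from the r between libraries, so an upward shift against WT of the same set is fixed by that choice, though its sign is not. Against WT of the same age, 478 genes were past 2-fold in opposite directions and 88 in the same direction. Independent lists would give 52.4 genes lower in KO and higher in KI, where 326 were seen, and 39.4 higher in both, where 52 were seen. Against WT of the same set, 69 protein-coding genes were past 2-fold in the same direction in KO and in the KI mean, 44 higher and 25 lower, where independent lists would give 1.88 and 1.49. Both KI libraries were past 2-fold in 35 of the 69, 20 higher and 15 lower, and with KI replicate 1 or 2 alone the count was 106 or 69. With the KI mean another 4 went in opposite directions (14 or 13 with replicate 1 or 2 alone), Cxcr6, Il10 and Gm4245 higher in KO and lower in KI, and Hist1h4c the reverse. Genes higher in both included Ifitm2, Lgals3, Gzmb, Il1r2, Il4, Ccl1 and Lilrb4, and genes lower in both included Klrg1, Cd86, Ccr9, Ccr6, Dtx1, Cd79a and Ms4a1, all named after their values were seen. Of those higher, Lgals3, Gzmb and Il4 were not past 2-fold in both KI libraries against WT at 6 weeks, where the KI mean lay at -0.07 for Lgals3 and 0.71 for Gzmb. Cd79a and Ms4a1 are B cell genes, and the B cell list had medians of -1.15 in KI and -1.14 in KO against WT of the same set.

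**Figure D4:**
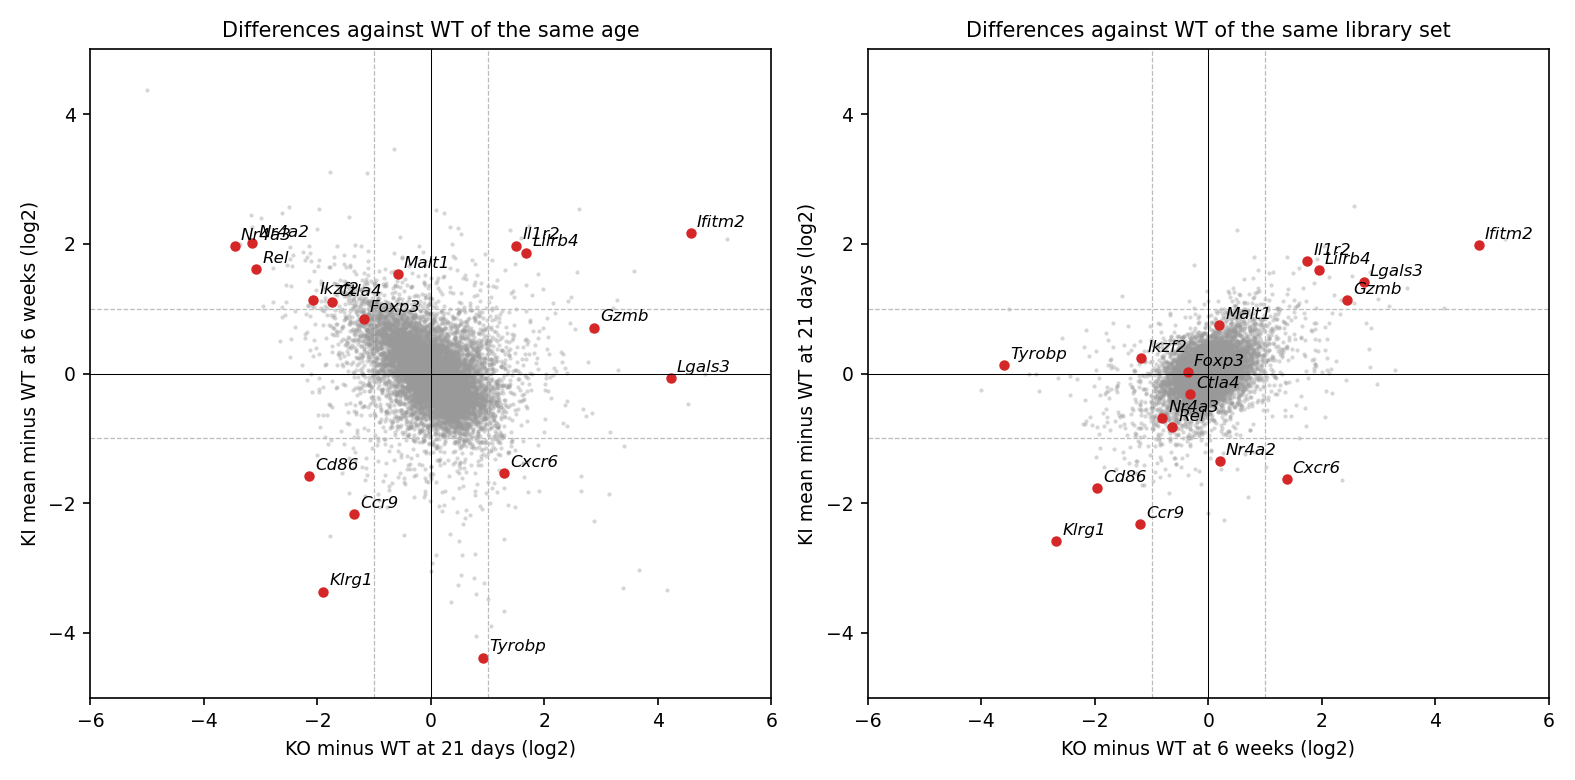
Log2 difference of KO (horizontal) and of the KI mean (vertical) for protein-coding genes, left against WT of the same age and right against WT of the same library set, with dashed lines at 2-fold and named genes in red. The Pearson r across genes is -0.396 on the left and 0.406 on the right.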

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

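The tests of explanations and the fit of the difference between genotypes were chosen after the results were seen, except that the 12 further myeloid genes were picked before their values were seen.

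KO and KI differed from WT of their own age in opposite directions in many genes. There were 199 genes past 2-fold higher in both KI libraries and past 2-fold lower in KO, 104 of them protein coding, and 114 genes the other way, 41 of them protein coding. The difference between the genotypes was not tested for these counts, which rest on every library moving one way. A limma fit of the KI difference minus the KO difference called 1 gene, mt-Tp (adjusted p = 0.0155), with 1887 genes at an unadjusted p under 0.05. Mt-Tp had 7832 scaled FPKM in WT at 6 weeks and 11544 in KO and was listed at 0 in the other libraries, so it followed the library sets. The spread in that fit comes from the KI pair alone, and its contrast runs along the sets. It therefore cannot tell a difference between genotypes from one between sets.

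Opposite effects of deletion and of the C472A allele are not decided here. Over protein-coding genes the correlation against WT of the same set was 0.406 (0.387 and 0.271 with KI replicate 1 or 2 alone). Opposite effects alone would give a value under 0. That comparison mixes stated ages, in opposite directions for KO and KI. Its controls were chosen by the r between libraries, which fixes an upward shift of this correlation, though not its sign. The size of that shift is not known, so a value above 0 does not exclude opposite effects. The sets crossed by each age-matched comparison stay a candidate explanation, and over all genes the correlation turned to 0.190 against WT of the same set. That turn does not decide it, since the sets were read from the same r. The value of 0.190 rests mostly on KI replicate 1, with 0.251 for it alone and 0.068 for replicate 2.

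The split of the libraries itself has 3 explanations. Age as labelled is argued against, since a WT library had up to 0.0665 more correlation with libraries of the other age than with those of its own. A difference in library preparation or sequencing may account for the split, since the length that Cufflinks subtracts also differs between the sets, with a gap of 31.7 nt between their quartiles over genes. That length by itself does not explain the split, which was kept over 9430 protein-coding genes with a transcript of 1000 nt or more. There r was 0.961 for WT at 6 weeks with KO and 0.948 for the WT libraries. Exchanged age labels of the WT libraries stay open, as each set would then hold 1 age. The smallest gap in r toward the other age, 0.0387, does not decide this, since the split was read from the same r, and no other value here does. The labels give no batch, so both explanations may hold together.

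Genes of myeloid and erythroid cells were high in WT at 6 weeks. Age as labelled is not settled by the KI libraries. The median of the myeloid list in the KI mean at 6 weeks was only 0.32 (0.318) above WT at 21 days. A bar of at least 1 for an age effect was set after the data were seen. KI replicates 1 and 2 both lay below WT at 6 weeks, but by unlike amounts, with medians of -1.32 and -2.61. KI also differs from WT in genotype, so these values do not decide it. RNA of other cells in that library stays a candidate explanation. Of 12 further myeloid genes, outside the fixed lists, 9 were tested and 8 were highest there, among them Cfp at 12.5 scaled FPKM against at most 3.52 elsewhere. Ifi30 was highest in KO. This result does not favour that explanation over others. In the myeloid list 9 of 10 genes were already highest there, and further myeloid genes would tend to follow whatever the cause. For erythroid genes no such test was made. The sort for CD4 and YFP is meant to remove such cells, but the labels give no purity. An effect of age in WT mice alone was not tested.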

How the results depend on the processing

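The choices of protein-coding genes, of WT of the same set and of both WT libraries were made after seeing the data. The filter named outside multigene families below dropped entries with a status other than OK and the classes that the naming rule leaves out. These include Gm and Rik symbols and the mitochondrial genome, with mt-Tp, while some families, such as Ifitm genes, stayed in. Of the named genes, 49 of 55 for KI and 52 of 57 for KO kept their direction with FPKM as deposited, 54 of 55 for KI with quantile normalization, and all under the other settings of scaling and pseudocount and for the WT ages. Those past 2-fold (37, 42 and 20) all kept it, where a change of sign needs a shift of more than 1 on the log2 scale. Of the values that answer a comparison, 36 stayed the same, 45 moved and 3 reversed; of the others, 595 stayed the same, 256 moved, 7 reversed, 12 became stronger and 18 weaker. The limma count for KI (1 gene) was 2 with FPKM as deposited and with quantile normalization, 50 with a pseudocount of 0.1, 0 with no filter (2841 at an unadjusted p under 0.05) or without trend (1165), 25 at a mean of 5 or more, 12 outside multigene families, 20 with robust fitting, 15 over protein-coding genes, 0 against WT of the same set, with all (240) or with protein-coding genes (202), and 0 to 0 leaving out either KI library in the fit that ignores age (369 and 316). The count by size for KI (656) was 1055 and 207 with pseudocounts of 0.1 and 5, 323 at a mean of 5 or more, 398 outside multigene families, 215 at 3-fold, 384 over protein-coding genes, 134 against WT of the same set, 71 against both WT libraries, and 1260 to 1492 leaving out 1 KI library, where 1 library decides alone. The KO count (1613) was 590 with a pseudocount of 5, 934 at a mean of 5 or more, 545 at 3-fold, 632 against WT of the same set, 351 against both WT libraries, 0 by limma on 4 means (1171 at an unadjusted p under 0.05) and 8 by limma with both WT libraries as replicates. The count between WT ages (967) was 1498 and 364 with pseudocounts of 0.1 and 5, 528 at a mean of 5 or more, 565 outside multigene families and 525 over protein-coding genes. A stricter filter or fold lowers a count by size by construction, but not a limma count; for the other changes the cause was not tested. The correlation of KO with KI (-0.445) was -0.397 and -0.507 with pseudocounts of 0.1 and 5, -0.406 with no filter, -0.525 at a mean of 5 or more, -0.429 outside multigene families, -0.396 over protein-coding genes and -0.414 to -0.402 leaving out 1 KI library; against WT of the same set it reversed to 0.190 (0.251 and 0.068 with KI replicate 1 or 2 alone), and to 0.406 over protein-coding genes (0.387 and 0.271). Malt1 in KI (1.53) moved to 0.75 (0.749) against WT of the same set, and in KO (-0.59) reversed to 0.20 (0.197). With an estimated correlation the calls of lists were lost, in a run that could hardly call any list. Against WT of the same set the direction of the camera test reversed for the KI lists erythroid and platelet (adjusted p = 0.801), immediate early TCR response (0.00652), mitochondrially encoded (3.6e-04) and myeloid cell (0.513). Erythroid and platelet and myeloid cell were not called there. The median of immediate early TCR response was under 0 against both controls, at -0.19 and -0.65. For mitochondrially encoded the direction also reversed against both WT libraries (0.944). The KO lists effector Treg and myeloid cell moved to percentiles 100 and 0. The shift of the median of all genes with FPKM as deposited was -0.26 for KI and 0.35 for KO and the WT ages; scaling to TPM moved that of KI against WT of the same set by 0.15. Depth limits WT at 6 weeks and KO most, at 7.26 and 8.28 M fragments. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers.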

Other observations

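The test of a shared change below was chosen after the results were seen, and the genes of the next 2 paragraphs were picked after their values were seen.

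The KI libraries differed from each other in single genes, and no list was tested for that difference. Tnfaip3, which restrains NF-kB signalling, had 864 scaled FPKM in KI replicate 1 and 228 in replicate 2, Nfkbia 604 and 170, Zc3h12a, which encodes Regnase-1, 64.8 and 14.3, and Rel 40.5 and 16.2. WT at 21 days had 795, 479, 45.3 and 46.5 for these genes. Mki67, a marker of cycling cells, had 15.9 in replicate 1 and 49.9 in replicate 2, and Ikzf2 had 62.6 and 104. In all, 744 genes were past 2-fold between the pair, 468 of them higher in replicate 1.

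Some immunoglobulin transcripts were highest in the library labelled KO. Ighg1 had 164 scaled FPKM there, 48.0 in KI replicate 1 and 5.97, 0.912 and 0.964 in WT at 21 days, WT at 6 weeks and KI replicate 2. Igkc had 399 in KO against 17.2 to 110 in the other libraries, and Ighe had 15.5 against at most 1.98. Ighm was not, with 216 in KO, 299 in WT at 6 weeks and 122 to 205 in the others. Of 4 tested plasma cell genes, 3 were highest in KO. Xist, the RNA of the inactive X chromosome, had 11.9 in KO and at most 1.17 elsewhere, and Y-linked genes were read in every library. Of these, Ddx3y had 7.04 in KO and 11.8 to 25.5 elsewhere, Kdm5d 2.88 and 5.15 to 9.54, Uty 1.26 and 2.27 to 6.36, and Eif2s3y 43.7 in KO, 41.3 in WT at 6 weeks and 48.7 to 60.4 in the others. Whether the KO library holds RNA of both sexes was not tested.

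A hypothesis is that both Malt1 genotypes share a change that the library sets hide in age-matched comparisons. Over protein-coding genes the KO difference from WT of the same set had r = 0.406 with the KI difference (0.387 and 0.271 with KI replicate 1 or 2 alone) and 0.0624 with the difference between the KI libraries. Against it, 23 protein-coding genes were past 2-fold in every mutant library against every WT library, and 2 of the other 9 splits of the 5 libraries into 2 and 3 gave more, 47 and the 108 of the library sets. Markers of B cells, another cell type, were among the genes lower in both genotypes against WT of the same set. With 10 splits no share under 0.05 can be had, the KO arm is 1 library, and stated age differs within each set, so the data do not decide whether a shared change may exist.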
